A study of Homo sapiens with 16 samples.

How the data were processed

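The series holds RNA sequencing of human macrophages grown from CD14+ blood monocytes of healthy donors in M-CSF, in 16 libraries. Per the labels these are stranded total RNA libraries with and without IFN-γ, mRNA libraries after control (siCtrl) or MAF-targeted (siMAF) siRNA, and mRNA libraries after an adenovirus that carries GFP (AdGFP) or MAF (AdMAF), each with and without IFN-γ. Each of the 8 groups had 2 libraries. IFN-γ was given at 100 U/ml for 48 h, with M-CSF at 10 ng/ml and 10% serum. Per the submitters' processing notes, FastQC, Trim Galore, STAR 2.5.2b, Cufflinks 2.2.1 and the genome build hg19 (GRCh37) were used.

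The authors deposited 3 gene tables whose values are RPKM (reads scaled by transcript length in kilobases and by the number of mapped reads), and these deposited RPKM values were the starting point. The tables listed 23494 gene symbols for total RNA and 21847 for each of the siRNA and adenovirus tables, and 0 columns of sample values were left unmapped. Each table was normalized on its own, so tests were run within a table and never across tables. No read counts were used. The spacing of the lowest RPKM values gave the relative depth within a table: 0.946 to 1.08 of the first library in the siRNA table and 1 to 1.95 in the adenovirus table. In the total RNA table the spacing gave a ratio of 0.883 for the 2 libraries of replicate 1, and no depth could be recovered for those of replicate 2. Precision therefore rests on the spread between libraries, and no counting interval was computed. An RPKM of exactly 0 can be a failed estimate as well as no expression. RPS18, TAP1, PSMB8, PSMB9, HLA-E and TNF were listed at 0 in every library of the siRNA and adenovirus tables, so their levels there are unknown, and for a named gene with a library at 0 the value of each library is given.

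Values were analysed as log2(RPKM + 1) in genes with an RPKM of at least 1 in at least 2 libraries of the table, which left 11435 genes for total RNA, 10458 for siRNA and 11171 for adenovirus. The pseudocount of 1 makes log2 changes understate the change of genes with low RPKM. XIST, TSIX and Y-linked genes were left out of every fit and table (97, 95 and 95 symbols). Groups were compared with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The adenovirus table was fitted once with 4 group means over its 8 libraries, which gave MAF against GFP virus without and with IFN-γ, IFN-γ against no IFN-γ under each virus, and the interaction (the difference between the IFN-γ effects of the viruses). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Nothing in the labels says whether replicates are separate donors, separate cultures or repeated libraries, or whether donors are shared between groups or tables. The p-values therefore measure only the spread between these samples, which may be technical.

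The comparisons, filters, gene lists, naming rule and all alternatives except 2 were chosen before the data were examined. MAF was reported in every library. Per contrast the 6 largest rises and 6 largest falls were named (3 and 3 for IFN-γ under AdMAF) among genes that passed, whose groups did not overlap and whose higher group had a mean RPKM of at least 5. For each list described, up to 4 members that passed with the largest absolute log2 change could be named, or, if none passed, the 2 with the highest mean RPKM. CD163, MRC1, MERTK, MSR1 and IRF1 could be named in every contrast. Noncoding symbols (LOC, LINC, MIR and similar), ribosomal pseudogenes and antisense genes were tested but not named among the top genes. Genes named outside this rule are marked as chosen after their values were seen.

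In all, 33 gene lists covering interferon responses, macrophage functions, metabolism, stress and the markers of other blood cell types were written down, and those with at least 5 measured members were tested: 26 for total RNA, 25 for siRNA and 24 for adenovirus. The test was limma's camera, which compares a list's genes with all other genes, at a preset correlation between genes of 0.01, with adjustment over the lists of a contrast. As alternatives, camera was run with an estimated correlation, and fry tested whether a list's genes moved, on balance, one way. A call lost with an estimated correlation does not by itself show that the genes of a list vary together. Members were counted as passing over all genes tested and adjusted over the list alone. A pair of lists was also carried between tables: genes that fell with IFN-γ in total RNA (adjusted p under 0.05 and a log2 change of −1 or lower), and genes lower in siMAF. Since 0 genes passed in the siRNA table, the latter was the 200 genes with the lowest moderated statistic, as the fallback rule fixed. These 12 list tests were adjusted together. Log2 changes of 5 pairs of contrasts that share no library were correlated across genes, without a p-value, since genes are not independent replicates.

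The alternatives were a pseudocount of 0.1, no filter, a filter at an RPKM of 5, quantile normalization, median centring, a prior without a trend, an adjusted p under 0.10, a fold of at least 2, the replicate number as a block, only the 4 libraries of a contrast, and leaving out each library in turn. Where that left 1 library in a group, the lone sample was assumed to vary like the other groups. A replicate block within each virus, and leaving out both AdGFP replicate 2 libraries, were chosen after seeing the data. The models were tested on simulated data with 50 altered genes per fold size, all sizes together, built on the spread of each table. The simulated noise was independent between libraries, without deviations shared by libraries of a replicate number. The recovered shares hold for such data only. A check for mixed-up libraries compared which of the left-out transcripts were present between libraries with the same replicate number, as counts only.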

Results

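The samples were primary human macrophages derived from blood monocytes, in 16 libraries that form 8 groups of 2. The total RNA table held untreated and IFN-γ-treated macrophages, the siRNA table held siCtrl and siMAF macrophages, and the adenovirus table held AdGFP and AdMAF macrophages, each untreated or given IFN-γ. The series title names the question. It is whether IFN-γ lowers genes of M2 macrophages through MAF, a transcription factor of that state. Summed RPKM per library ran from 402608 to 477273 in total RNA, from 387896 to 434701 after siRNA and from 380805 to 557609 after adenovirus. Across genes that passed the filter, the 2 libraries of a group correlated at Pearson's r = 0.79 and 0.841 in total RNA, at 0.979 and 0.975 after siRNA, and at 0.937 to 0.968 after adenovirus. These are correlations across genes, which are not independent replicates. RPKM is given as mean ± SD and log2 changes as estimate ± SE, all with n = 2 libraries per group, and each adjusted p is from limma.

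MAF stood at 35.2 and 36.5 RPKM in the untreated and at 5.26 and 9.004 RPKM in the IFN-γ libraries of total RNA. In the siRNA table it stood at 43.0 and 32.5 RPKM in siCtrl and at 11.4 and 8.53 RPKM in siMAF. In the adenovirus table it stood at 65.7 and 93.8 RPKM in untreated AdGFP and at 11.4 and 20.6 RPKM in AdGFP with IFN-γ. With AdMAF, where the value includes the transgene, it stood at 769 and 192 RPKM untreated and at 713 and 544 RPKM with IFN-γ.

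**Figure D1:**
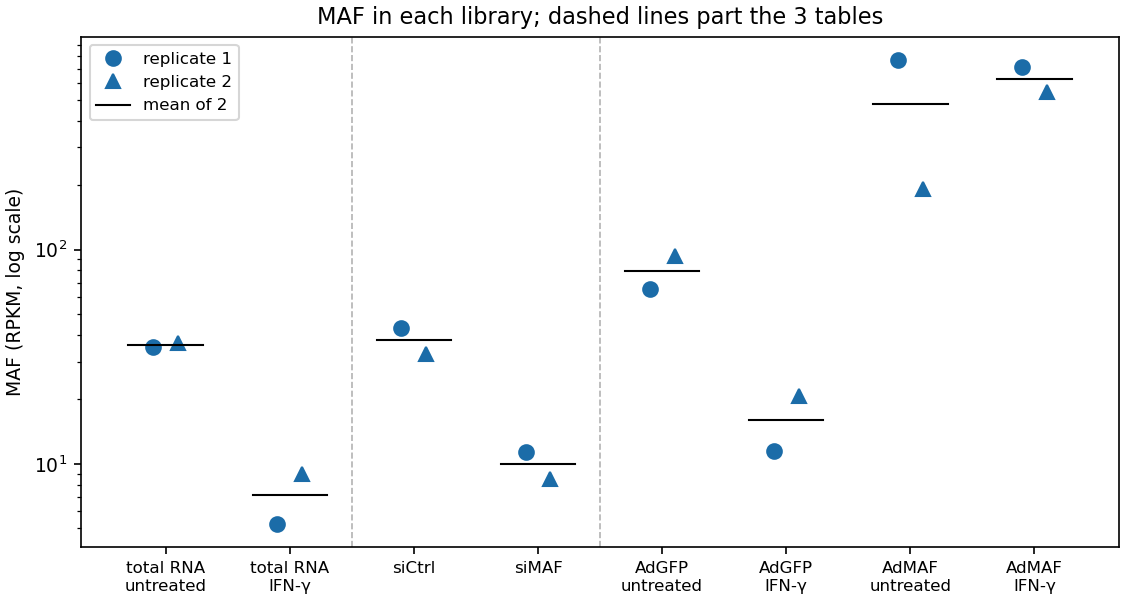
MAF in each of the 16 libraries (y axis, RPKM, log scale) by group (x axis); circles are replicate 1, triangles are replicate 2, short lines are means of 2, and dashed lines part the 3 separately normalized tables. MAF stood lower with IFN-γ in total RNA (7.13 against 35.8 RPKM) and under AdGFP (16.0 against 79.7 RPKM), while the AdMAF means were 480.2 RPKM untreated and 628.7 RPKM with IFN-γ.

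Does IFN-γ change the expression state of these macrophages? In total RNA, MAF fell with IFN-γ (log2 change −2.22 ± 0.30, 7.13 ± 2.65 against 35.8 ± 0.944 RPKM, adjusted p = 0.0452). The largest rises included IFN-γ response genes. CXCL9, a T cell-attracting chemokine, rose from 0.581 ± 0.726 to 884 ± 8.11 RPKM (log2 change 9.21 ± 0.40). IDO1, which breaks down tryptophan, rose from 1.52 ± 0.514 to 575 ± 120 RPKM (7.84 ± 0.28). The guanylate-binding proteins GBP5 and GBP1, which act against microbes inside cells, rose by 7.62 ± 0.27 and 7.35 ± 0.23. The adjusted p was 0.0137 for each of these 4 genes. The chemokine CXCL10 (7.82 ± 0.42, adjusted p = 0.0153) and the cytidine deaminase APOBEC3A (6.73 ± 0.38, adjusted p = 0.0153) were the other two of the 6 largest rises.

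Of the genes that fell with IFN-γ in total RNA, SEPP1, a selenium transport protein, fell from 1577 ± 314 to 0.496 ± 0.625 RPKM (log2 change −10.09 ± 0.40). RNASE1, a secreted ribonuclease, fell from 1419 ± 229.9 to 1.30 ± 0.532 RPKM (−9.28 ± 0.28). The clotting factor subunit F13A1 (−7.09 ± 0.20), the lysosomal protease LGMN (−5.76 ± 0.22) and the receptor GPR34 (−5.58 ± 0.18) fell too, each of the 5 with an adjusted p of 0.0137. CD163, the haemoglobin scavenger receptor, fell from 254 ± 135 to 4.67 ± 1.55 RPKM (−5.41 ± 0.49, adjusted p = 0.0252). MERTK, a receptor for the uptake of dead cells, fell from 12.3 ± 0.426 to 1.90 ± 0.15 RPKM (−2.20 ± 0.18, adjusted p = 0.0224). For the scavenger receptor MSR1 the change was −1.46 ± 0.33 (adjusted p = 0.111). The mannose receptor MRC1 gave −2.88 ± 1.75 (adjusted p = 0.421), a value that is uncertain since hg19 holds a near-identical copy of this gene.

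In this comparison 627 of 11435 genes passed, 366 higher and 261 lower with IFN-γ, all by at least 2-fold. At random 572 genes would have an unadjusted p under 0.05, and 2708 had one. In 53.4% of the genes the groups did not overlap, where chance gives 33.3%. On simulated data with 11063 genes run, 0% of changes of log2 1, 60% of log2 2, 82% of log2 3 and 90% of log2 4 were recovered, with 19 unchanged genes called. Without untreated replicate 2, 0 genes passed limma (1428 at an unadjusted p under 0.05), and 0 without IFN-γ replicate 2 (1183). The changes stayed about as large: of the 627 genes, 531 and 533 were still tested, all in the same direction and at a median of 0.99 of the log2 change in both cases, with median standard errors 1.45 and 1.61 times as large. There were 185 and 49 genes that passed without untreated replicate 1 and IFN-γ replicate 1, of which 162 and 49 were among the 627. MAF itself had log2 changes of −2.24, −1.88, −2.19 and −2.56 (adjusted p = 0.0972, 0.116, 0.259 and 0.236) without untreated replicate 1, IFN-γ replicate 1, untreated replicate 2 and IFN-γ replicate 2. Its adjusted p was also 0.0668 with no filter and 0.0549 with median centring.

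By gene list, 26 of 38 measured IFN-γ response genes rose and 0 fell (33 adjusted over the list alone; median log2 change 4.28; camera adjusted p = 1.37e-25, adjusted p = 0.322 with an estimated correlation). Among them was the transcription factor IRF1 (11.1 ± 1.04 to 181 ± 3.78 RPKM, 3.91 ± 0.19). Of 17 genes for MHC class I presentation 9 rose (11 over the list alone; median 1.94; adjusted p = 1.19e-09, 0.322 with an estimated correlation). The proteasome activator PSME2 rose by 4.38 ± 0.21 and the peptide transporter TAP1 by 3.48 ± 0.41 (adjusted p = 0.059 with no filter). Of 27 type I interferon-stimulated genes 12 rose (23 over the list alone; median 2.22; adjusted p = 5.01e-15, 0.322 with an estimated correlation). Among them the antiviral IFIT3 rose by 4.16 ± 0.20 and IFI27 by 6.17 ± 0.24. Of 19 genes for cholesterol synthesis and uptake 13 rose (18 over the list alone; median 1.99; adjusted p = 2.07e-14, 0.322 with an estimated correlation). Of 19 inflammatory cytokines and chemokines 6 rose and 2 fell (12 and 2 over the list alone; median 1.64; adjusted p = 2e-06, 0.322 with an estimated correlation). The monocyte attractant CCL2 rose by 4.999 ± 0.29 and the neutrophil attractant IL8 by 3.78 ± 0.25. Of 10 genes for tryptophan and arginine metabolism 4 rose (7 over the list alone; adjusted p = 3.22e-05, 0.322 with an estimated correlation). WARS, the tryptophan tRNA ligase, rose by 4.78 ± 0.22. Of 7 metallothioneins, which bind zinc and copper, 4 rose (7 over the list alone; adjusted p = 2.85e-06, 0.339 with an estimated correlation). MT2A rose by 6.02 ± 0.28. None of these gene calls passed without untreated replicate 2 or IFN-γ replicate 2, but the changes stayed about as large. They were 3.82 and 3.89 for IRF1, 4.33 and 4.25 for PSME2, 4.64 and 4.75 for WARS, and 5.72 and 6.02 for MT2A. The choice of called genes makes this likely. All 7 list calls were kept without each library in turn.

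The lists of the M2 state went the other way with IFN-γ. Of 21 surface markers of M2 and M-CSF macrophages 9 fell and 0 rose (12 adjusted over the list alone; median log2 change −2.04; adjusted p = 3.36e-07, adjusted p = 0.322 with an estimated correlation). Examples were the membrane protein MS4A4A (−4.83 ± 0.30), the folate receptor FOLR2 (−4.65 ± 0.37, from 67.7 ± 29.1 to 1.62 ± 0.0164 RPKM) and the scavenger receptor STAB1 (−4.53 ± 0.19, from 313 ± 8.81 to 12.6 ± 0.478 RPKM). Of 18 efferocytosis and phagocytic receptors 7 fell and 1 rose (11 and 4 over the list alone; median −1.44; adjusted p = 0.00307, 0.398 with an estimated correlation). MARCO, a scavenger receptor, fell by 3.72 ± 0.20. Of 18 secreted M2 factors 9 fell and 3 rose (10 and 4 over the list alone; median −2.17; adjusted p = 0.00416, 0.322 with an estimated correlation). The chitinase-like protein CHI3L1 of this list rose by 6.70 ± 0.35. Of 16 genes for iron handling 2 fell and 1 rose (5 and 1 over the list alone; median −0.51; adjusted p = 0.0294, 0.515 with an estimated correlation). The iron exporter SLC40A1 fell by 4.37 ± 0.26. The call for secreted M2 factors was lost without untreated replicate 1 (adjusted p = 0.52) and untreated replicate 2 (0.957), and that for iron handling without untreated replicate 1 (0.0935). None of the gene calls passed without untreated replicate 2 or IFN-γ replicate 2. Changes stayed about as large, such as −5.06 and −4.58 for MS4A4A and −4.56 and −4.57 for STAB1.

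Among the remaining lists of total RNA, higher than other genes with IFN-γ stood ATF4 targets (3 of 15 rose, 11 over the list alone; median log2 change 1.09; adjusted p = 2.54e-05, 0.322 with an estimated correlation), glycolysis (2 of 17 rose, median 0.92, adjusted p = 0.000484, 0.322) and oxidative phosphorylation (0 of 19 passed limma, median 0.51, adjusted p = 0.000361, 0.398). The same held for integrins and adhesion molecules (6 of 16 rose, including ICAM1 at 2.74 ± 0.27; adjusted p = 0.00311, 0.445 with an estimated correlation), apoptosis regulators (3 of 20 rose, adjusted p = 0.00311, 0.322) and complement components (6 of 17 rose and 1 fell, adjusted p = 0.00842, 0.445). The C1 inhibitor SERPING1 of the latter rose by 5.34 ± 0.42. Immediate early and heat shock genes also stood higher (1 of 16 rose, median 0.59, adjusted p = 0.00419, 0.379 with an estimated correlation). NK cell markers stood lower, with 0 of 6 past limma, 2 lower over the list alone, a median of −0.77 and an adjusted p of 0.00416 (0.381 with an estimated correlation). The complement call was lost without IFN-γ replicate 1 (adjusted p = 0.183) and IFN-γ replicate 2 (0.682), and the immediate early call without untreated replicate 1 (0.51). Lists that did not pass were MHC class II presentation (median 0.28, adjusted p = 0.393), macrophage transcription factors (0.36, 0.153; the early growth response factor EGR2 rose by 4.50 ± 0.29), lysosome and cathepsins (−0.26, 0.075) and dendritic cell markers (0.86, 0.153). Nor did lipid export and handling (−0.17, 0.441; the fatty acid-binding protein FABP4 fell by 3.54 ± 0.20), Toll-like receptor pathway (median 0.17, mean 0.08 and a test pointing down, 0.932) or proliferation (median 0.12, mean −0.11, 0.906). As everywhere in this comparison, the gene calls were lost without untreated replicate 2 or IFN-γ replicate 2. EGR2 still had a change of 4.27 in both cases.

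Too few members were measured to test T cell (2 in total RNA, 1 after siRNA, 1 after adenovirus), B cell (4, 1 and 2), platelet (2, 2 and 2), erythroid (2, 0 and 0), neutrophil (3, 4 and 2) and fibroblast markers (0 in each table). NK cell markers (1 after siRNA and 3 after adenovirus) and dendritic cell markers (3 after adenovirus) could be tested only in the other tables. The tables listed 0 of the 13 mitochondrially encoded transcripts.

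**Figure D2:**
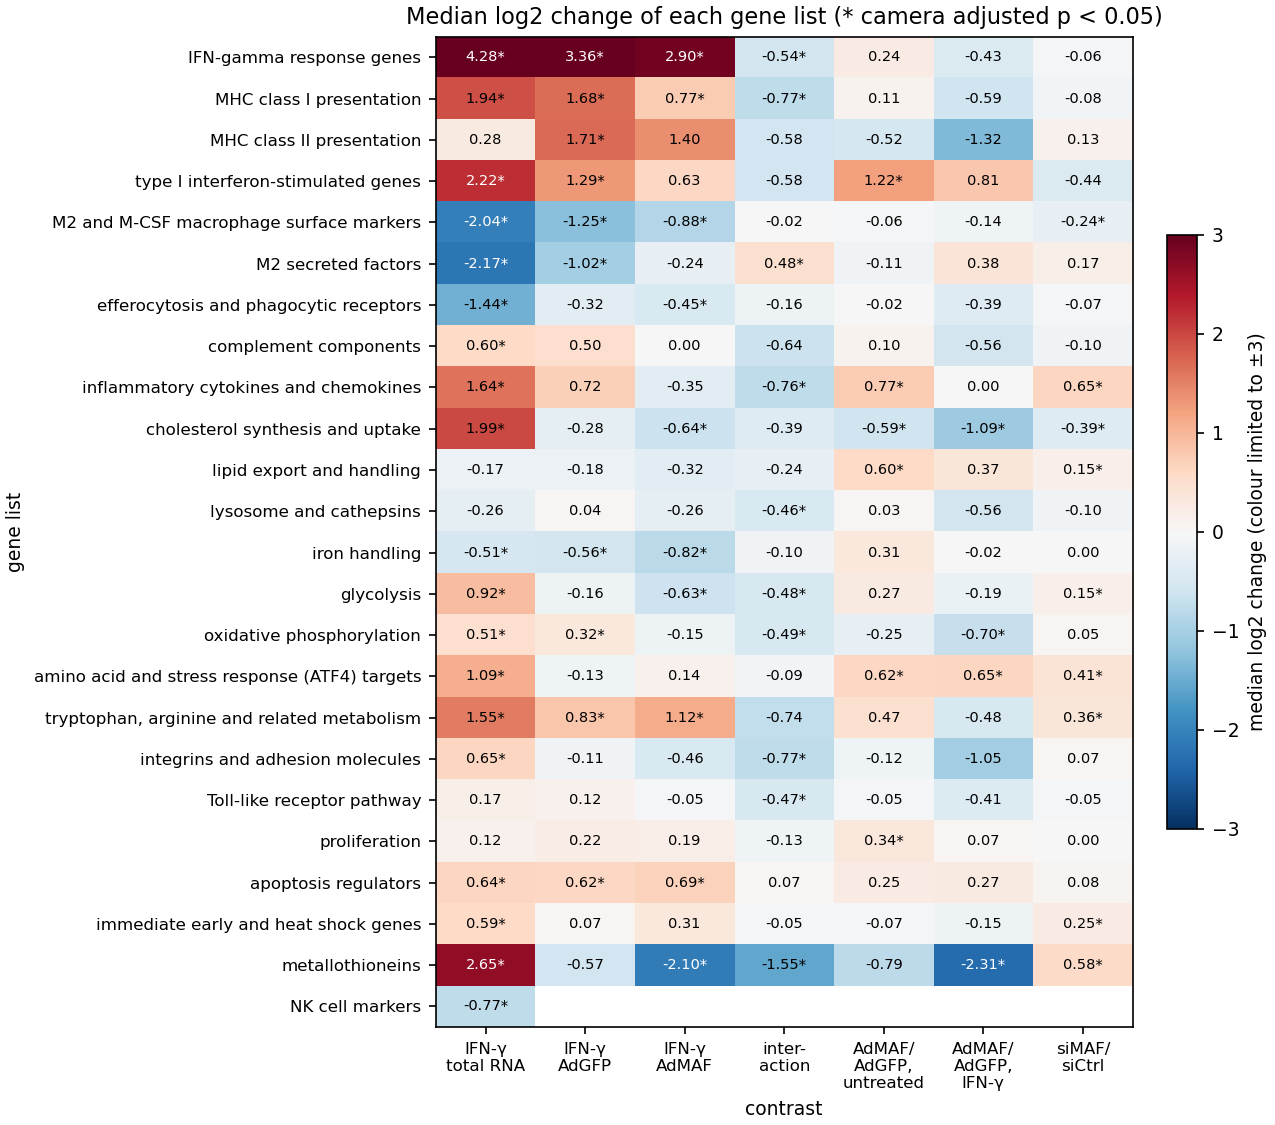
Median log2 change (cells, colour limited to ±3) of the gene lists with a camera adjusted p under 0.05 in at least 1 contrast (y axis), in the 7 contrasts (x axis); an asterisk stands for a camera adjusted p under 0.05 at the preset correlation. Surface markers of M2 and M-CSF macrophages had medians of −2.04, −1.25 and −0.88 with IFN-γ in total RNA, AdGFP and AdMAF, and −0.24 with siMAF.

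Which genes depend on MAF in macrophages without IFN-γ was addressed by siRNA. MAF was 9.95 ± 2.01 RPKM in siMAF and 37.7 ± 7.37 RPKM in siCtrl (log2 change −1.82 ± 0.20, lower in both siMAF libraries, adjusted p = 0.904). Among genes chosen after their values were seen, SEPP1 was 31.3 ± 5.85 against 129.6 ± 34.0 RPKM (−2.00 ± 0.24, adjusted p = 0.904) and the bile acid receptor GPBAR1 was 3.96 ± 0.402 against 11.1 ± 0.392 RPKM (−1.29 ± 0.10, adjusted p = 0.879). FOLR2 was 37.9 ± 31.8 against 131 ± 98.8 RPKM (−1.82 ± 0.88), and the inhibitory receptor CD200R1 had a log2 change of −0.996 ± 0.10. CD163 was 489 ± 243 against 466 ± 115 RPKM (0.00 ± 0.42) and MERTK was 64.5 ± 2.68 against 51.2 ± 3.503 RPKM (0.33 ± 0.10, adjusted p = 0.978). Of 10458 genes 0 passed limma and 512 had an unadjusted p under 0.05, against 523 by chance. The lowest adjusted p was 0.879, and groups did not overlap in 32.1% of genes, where chance gives 33.3%. Both chance levels assume that libraries vary independently, while same-number siRNA libraries deviated together (r = 0.79 across genes). Values near them therefore do not show that siMAF had no effect. A fit with the replicate number as a block is given below. With 10367 genes run on simulated data, 76% of changes of log2 1, 98% of log2 2, 94% of log2 3 and 100% of log2 4 were recovered, with 11 unchanged genes called. Those data had altered genes of all sizes together and noise that was independent between libraries. They do not show that siMAF changes of log2 1 or 2 would pass, and MAF (−1.82) and SEPP1 (−2.00) did not. The count stayed 0 without each library in turn (193 to 700 genes at an unadjusted p under 0.05), and the CD163 value was 0.25 without siCtrl replicate 1 and 0.52 without siMAF replicate 2.

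Although 0 genes passed limma with siMAF (512 at an unadjusted p under 0.05), 9 of 25 lists differed from other genes at the preset correlation, each with an adjusted p of 0.704 with an estimated correlation. Genes for cholesterol synthesis and uptake stood lower in siMAF (19 of 19 members below 0, median log2 change −0.39, adjusted p = 8.66e-14). The sterol sensor INSIG1 had −0.83 ± 0.19 and the enzyme FDPS −0.29 ± 0.11. Surface markers of M2 and M-CSF macrophages stood lower too (19 of 21 below 0, 2 lower adjusted over the list alone, median −0.24, adjusted p = 0.000306). Higher in siMAF stood ATF4 targets (15 of 15 above 0, median 0.41, adjusted p = 6.29e-06), immediate early and heat shock genes (median 0.25, 0.000414), metallothioneins (8 of 8 above 0, median 0.58, 0.00778; MT2A at 0.64 ± 0.41) and inflammatory cytokines and chemokines (median 0.65, 0.0134). CCL2 of that list was 2688 and 467 RPKM in siMAF against 931 and 460 RPKM in siCtrl (0.78 ± 0.94, and −0.49 without siMAF replicate 1). Tryptophan and arginine metabolism (median 0.36, adjusted p = 0.0134), glycolysis (0.15, 0.0205) and lipid export and handling (0.15, 0.0333) stood higher as well. The IFN-γ response genes did not (median −0.06, mean 0.07, adjusted p = 0.755). Without siMAF replicate 1, 5 lists passed. The calls were lost for inflammatory cytokines (adjusted p = 0.161), lipid export (0.0635), glycolysis (0.466), tryptophan metabolism (0.194) and metallothioneins (0.843, direction turned). Glycolysis was also lost without siCtrl replicate 1 (0.0723), and lipid export without siCtrl replicate 2 (0.428) and siMAF replicate 2 (0.118).

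Added MAF without IFN-γ was tested as AdMAF against AdGFP. In the check for mixed-up samples, 2 of 4 pairs with the same number and treatment did not match between the viruses. Differences between the viruses may therefore hold donor differences as well as effects of MAF. DHRS2, a dehydrogenase/reductase, rose, with 226 and 119 RPKM in AdMAF against 0 and 0.279 RPKM in AdGFP (adjusted p = 0.00648). The secreted protease HTRA3 rose from 0.365 ± 0.041 to 23.7 ± 10.7 RPKM (log2 change 4.10 ± 0.30, adjusted p = 0.013). IGFBP7, a binding protein for insulin-like growth factors, rose from 7.39 ± 0.764 to 92.0 ± 14.9 RPKM (3.47 ± 0.30, adjusted p = 0.0274). These 3 were all the genes that passed of 11171, with 629 at an unadjusted p under 0.05 against 559 by chance. In 33.4% the groups did not overlap, against 33.3% by chance. MAF, transgene included, had a change of 2.28 ± 0.64 (adjusted p = 0.857), with its AdMAF libraries at 769 and 192 RPKM. MERTK was 131 ± 4.54 against 68.0 ± 55.6 RPKM (1.22 ± 0.58, adjusted p = 0.857), and CD163 had a change of −0.33 ± 0.46 (0.00 without AdGFP untreated replicate 1). On simulated data with 10937 genes run, 8% of changes of log2 1, 76% of log2 2, 94% of log2 3 and 98% of log2 4 were recovered, with 7 unchanged genes called. Without AdGFP untreated replicate 1 or 2, 0 genes passed limma (1103 and 335 at an unadjusted p under 0.05), with DHRS2 at 0.101 and 0.117, HTRA3 at 0.112 and 0.241 and IGFBP7 at 0.204 and 0.333 (adjusted p). Their log2 changes stayed at a median of 0.98 and 1.02 of the full value, which the choice of called genes makes likely. Without AdGFP IFN-γ replicate 1 or 2, 1 gene passed (HTRA3 at 0.0524 and 0.0516, IGFBP7 at 0.0782 and 0.0778). Without AdMAF IFN-γ replicate 1 or 2 HTRA3 was lost (adjusted p = 0.0539 and 0.0529). Without AdMAF untreated replicate 1 or 2 IGFBP7 was lost (0.247 and 0.0552). With only the 4 libraries of the contrast DHRS2 alone passed (adjusted p = 0.0154, against 0.102 for HTRA3 and 0.0966 for IGFBP7). The count was 0 by limma with no filter (1120 at an unadjusted p under 0.05) and without both AdGFP replicate 2 libraries (428).

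By list, 6 of 24 differed between AdMAF and AdGFP without IFN-γ, each with an adjusted p of 0.922 with an estimated correlation and 0 members past limma. Type I interferon-stimulated genes stood higher in AdMAF (27 of 27 above 0, median log2 change 1.22, adjusted p = 5.72e-06). ISG15 stood at 2843 and 1554 RPKM in AdMAF against 1686 and 66.8 RPKM in AdGFP, and IFI6 at 2854 and 2641 against 2599 and 401 RPKM. Without AdGFP untreated replicate 2 this median was −0.45 (adjusted p = 0.295), and without both AdGFP replicate 2 libraries the list stood lower in AdMAF (adjusted p = 0.0373). Inflammatory cytokines and chemokines stood higher (median 0.77, adjusted p = 0.00899), with CCL2 at 4478 and 7745 against 8081 and 148 RPKM. Their call was lost and turned without AdGFP untreated replicate 2 (adjusted p = 0.457, CCL2 at −0.46) and lost without AdMAF untreated replicate 1 (0.133). Higher stood also ATF4 targets (median 0.62, 0.00231; 0.35 without AdGFP untreated replicate 2), lipid export and handling (0.60, 0.00899; 0.706 without AdMAF untreated replicate 2) and proliferation (0.34, 0.0213; 0.82 without AdGFP untreated replicate 1 and 0.051 without AdMAF untreated replicate 2). Genes for cholesterol synthesis and uptake stood lower in AdMAF (17 of 19 below 0, median −0.59, adjusted p = 0.00108), with FDPS at 41.0 ± 16.3 against 68.5 ± 12.4 RPKM. They lost the call without AdGFP untreated replicate 1 (0.691) and AdMAF untreated replicate 1 (0.0582). Lower, but not past the test, stood metallothioneins (9 of 9 below 0, median −0.79, adjusted p = 0.0574), and surface markers of M2 and M-CSF macrophages had a median of −0.06 (adjusted p = 0.463).

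Added MAF in the presence of IFN-γ was tested in the same way, and 123 of 11171 genes passed, 98 higher and 25 lower in AdMAF. Donor differences between the viruses may be part of this too, given the pairs that did not match. MAF, transgene included, rose from 16.0 ± 6.52 to 629 ± 119.6 RPKM (log2 change 5.25 ± 0.64, adjusted p = 0.023). DHRS2 rose (147 and 295 RPKM against 0 and 0.396 RPKM, adjusted p = 0.00484), as did HTRA3 (25.7 and 27.3 against 0 and 0.0644 RPKM, adjusted p = 0.00484) and the membrane protein TMEM100 (87.7 and 88.2 against 0 and 0.121 RPKM, adjusted p = 0.0191). BAMBI, a decoy receptor of TGF-β signalling, rose by 4.83 ± 0.80 (adjusted p = 0.0476) and ID3, an inhibitor of DNA binding, rose from 9.68 ± 2.92 to 262 ± 114 RPKM (4.58 ± 0.56, adjusted p = 0.0232). The falls included the metallothionein locus MT1L (−3.43 ± 0.54, adjusted p = 0.045), the chemokine CCL19 (−3.25 ± 0.46, adjusted p = 0.0344) and the protease-like ADAMDEC1, from 175 ± 15.2 to 20.3 ± 1.18 RPKM (−3.04 ± 0.39, adjusted p = 0.0237). The metalloprotease ADAM28 (−2.73 ± 0.36), the ADP receptor P2RY13 (−2.62 ± 0.38) and AOAH, an enzyme that inactivates bacterial lipopolysaccharide (−2.61 ± 0.40), fell too. MERTK was 62.6 ± 2.93 against 6.79 ± 3.34 RPKM (3.10 ± 0.58, adjusted p = 0.0622). It passed without AdGFP untreated replicate 1 (0.0276) and AdGFP untreated replicate 2 (0.0282). CD163 (−0.63 ± 0.46, adjusted p = 0.443) did not pass. DDIT4, a stress-induced inhibitor of mTORC1, rose from 2.71 ± 0.367 to 22.4 ± 7.40 RPKM (2.62 ± 0.43, adjusted p = 0.0476). At an unadjusted p under 0.05 stood 2556 genes against 559 by chance, and 56.3% did not overlap against 33.3% by chance. With 10934 genes run on simulated data, 22% of changes of log2 1, 82% of log2 2, 96% of log2 3 and 100% of log2 4 were recovered, with 10 unchanged genes called. Without AdGFP IFN-γ replicate 1, 0 genes passed limma (2143 at an unadjusted p under 0.05), and 10, 2 and 1 passed without AdGFP IFN-γ replicate 2, AdMAF IFN-γ replicate 1 and AdMAF IFN-γ replicate 2. Without either AdGFP untreated library 65 passed and without either AdMAF untreated library 215. Of the 13 named genes that passed, 0, 3, 1 and 1 kept the call without AdGFP IFN-γ replicate 1, AdGFP IFN-γ replicate 2, AdMAF IFN-γ replicate 1 and AdMAF IFN-γ replicate 2. There were 10 that kept it without either AdGFP untreated library. Of the 123 genes, 123, 123, 117 and 117 were still tested without these libraries of the IFN-γ groups in the same order, all in the same direction and at a median of 1, 1, 0.98 and 1.02 of the log2 change. These genes were chosen by their calls, which limits how far their changes could move. The count was 51 with no filter (23 of them among the 123), 76 with quantile normalization (73), 246 with only the 4 libraries of the contrast (115) and 0 by limma without both AdGFP replicate 2 libraries (1844 at an unadjusted p under 0.05). Of the 13 named genes, 2, 10, 13 and 0 kept the call under these settings.

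By list, 4 of 24 differed between AdMAF and AdGFP with IFN-γ, each with an adjusted p of 0.849 with an estimated correlation. Metallothioneins stood lower in AdMAF (9 of 9 below 0, 1 fell and 5 fell adjusted over the list alone, median log2 change −2.31, adjusted p = 0.00158). Lower stood genes for cholesterol synthesis and uptake (17 of 19 below 0, median −1.09, adjusted p = 0.00214), with FDPS at 23.8 ± 7.23 against 57.2 ± 19.1 RPKM. Oxidative phosphorylation stood lower too (17 of 19 below 0, median −0.70, adjusted p = 0.00579), with the cytochrome c oxidase subunit COX7C at 257 ± 93.6 against 464 ± 33.8 RPKM. ATF4 targets stood higher (1 of 13 rose, DDIT4, and 6 adjusted over the list alone; median 0.65, adjusted p = 0.0374). Macrophage transcription factors did not pass as a list (2 of 36 rose, MAF and ID3; median 0.07, adjusted p = 0.577). Nor did surface markers of M2 and M-CSF macrophages (2 higher and 3 lower over the list alone; median −0.14, mean 0.02, adjusted p = 0.857) or IFN-γ response genes (median −0.43, adjusted p = 0.159). The call for oxidative phosphorylation was lost without AdMAF IFN-γ replicate 1 (adjusted p = 0.0723) and that for ATF4 targets without AdGFP IFN-γ replicate 2 (0.0955). The count of lists was 7 without AdGFP untreated replicate 1 or 2, AdGFP IFN-γ replicate 1 or AdMAF IFN-γ replicate 2, and 8 without AdGFP IFN-γ replicate 2. DDIT4, MAF, ID3 and MT1L were not called without any 1 library of the AdGFP IFN-γ and AdMAF IFN-γ groups (adjusted p for ID3 0.0921, 0.116, 0.175 and 0.141), nor MT1L without AdGFP untreated replicate 1 (0.0736) or 2 (0.0735).

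Under the control virus, IFN-γ called 293 of 11171 genes, 152 higher and 141 lower, in the fit over all 8 libraries. With only the 4 libraries of the contrast 18 passed (14 higher and 4 lower, 17 of them among the 293), including 9 of the 23 named genes. MAF was 16.0 ± 6.52 against 79.7 ± 19.8 RPKM (log2 change −2.28 ± 0.64, adjusted p = 0.129; 0.0419 without AdMAF untreated replicate 1 and 0.0429 without AdMAF untreated replicate 2). Rises included IDO1 (7.20 ± 1.22, adjusted p = 0.0324) and the membrane protein FAM26F (6.50 ± 0.48, adjusted p = 0.00247). They also included GBP5 from 11.2 ± 6.21 to 914 ± 408 RPKM (6.26 ± 0.55, adjusted p = 0.00427) and the tumour suppressor RARRES3 from 9.31 ± 1.75 to 770.4 ± 105 RPKM (6.23 ± 0.39, adjusted p = 0.00172). LGALS17A (6.25 ± 0.22, adjusted p = 0.000132) and the matrix protein HAPLN3 (6.01 ± 0.42, adjusted p = 0.00247) completed the 6 largest. Falls included the amino acid transporter SLC16A10 (−5.04 ± 0.53), the matrix proteins THBS1 (−4.63 ± 0.60) and VCAN (−4.23 ± 0.73), DDIT4 (−4.51 ± 0.43), LGI2 (−4.37 ± 0.31) and the lipid receptor S1PR1 (−4.19 ± 0.61). IRF1 rose from 22.4 ± 9.41 to 388 ± 52.1 RPKM (4.11 ± 0.35, adjusted p = 0.00427). For CD163 the change was −1.43 ± 0.46 (adjusted p = 0.184) and for MERTK −2.93 ± 0.58 (adjusted p = 0.0529; 0.0187 without AdGFP untreated replicate 2). At an unadjusted p under 0.05 stood 1751 genes against 559 by chance, and 43.6% did not overlap against 33.3% by chance. On simulated data with 10943 genes run, 10% of changes of log2 1, 78% of log2 2, 96% of log2 3 and 100% of log2 4 were recovered, with 9 unchanged genes called. The count was 180 and 134 without AdGFP untreated replicates 1 and 2, 70 without AdGFP IFN-γ replicate 1, and 133 and 132 without AdMAF IFN-γ replicates 1 and 2. IDO1 lost its call without each of these 5 libraries (adjusted p = 0.0591, 0.133, 0.0887, 0.0736 and 0.0726). VCAN lost it without AdGFP IFN-γ replicate 1 (0.135) or 2 (0.0973) and AdMAF IFN-γ replicate 1 (0.0673) or 2 (0.0661), and THBS1 without AdGFP IFN-γ replicate 1 (0.0753). For S1PR1 this held without AdGFP untreated replicate 1 (0.0689) or 2 (0.093) and AdGFP IFN-γ replicate 1 (0.112) or 2 (0.0607). All of the 293 genes still tested without each of these 4 AdGFP libraries kept their direction (293, 293, 287 and 287), at a median of 1.02, 0.98, 0.96 and 1.04 of the log2 change. With no filter 118 genes passed (102 of them among the 293, with 15 of the 23 named genes), and without both AdGFP replicate 2 libraries 113 (67, with 17 of the 23).

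By list, 10 of 24 moved with IFN-γ under AdGFP. IFN-γ response genes led, with 19 of 34 higher and 0 lower (30 adjusted over the list alone; median log2 change 3.36; adjusted p = 2.77e-31, adjusted p = 0.502 with an estimated correlation). Among them were the feedback inhibitor SOCS1 (5.77 ± 0.50) and ANKRD22 (5.81 ± 0.27). Of 10 genes for MHC class I presentation 3 rose (4 over the list alone; median 1.68; adjusted p = 0.00066, 0.502 with an estimated correlation). They included PSME2 (3.39 ± 0.53) and the immunoproteasome subunit PSMB10 (2.19 ± 0.33). MHC class II presentation (0 of 9 past limma, median 1.71, adjusted p = 0.00719, 0.75 with an estimated correlation), type I interferon-stimulated genes (0 of 27, 1.29, 0.00179, 0.819), apoptosis regulators (0 of 20, 0.62, 0.00066, 0.502) and oxidative phosphorylation (0 of 19, 0.32, 0.0143, 0.811) stood higher too. So did tryptophan and arginine metabolism (2 of 9 rose, adjusted p = 0.000896, 0.502 with an estimated correlation), with WARS at 5.55 ± 0.50. Secreted M2 factors stood lower (2 of 20 fell, 7 over the list alone; median −1.02; adjusted p = 0.00289, 0.502 with an estimated correlation). The members that fell were the anti-inflammatory cytokine IL10 (−2.49 ± 0.40, 6.69 ± 4.64 against 38.0 ± 0.383 RPKM) and the growth factor IGF1 (−1.96 ± 0.26). Surface markers of M2 and M-CSF macrophages stood lower with 0 of 22 past limma and 10 lower and 2 higher over the list alone (median −1.25, adjusted p = 0.00719, 0.502 with an estimated correlation). Iron handling stood lower with 1 of 13 past limma (median −0.56, adjusted p = 0.0114, 0.502 with an estimated correlation), the metal transporter SLC11A1 (−3.75 ± 0.35). Of 14 complement components 3 rose, among them C1QB (4.15 ± 0.75) and SERPING1 (4.04 ± 0.31), without a list call (adjusted p = 0.109). Without AdGFP untreated replicate 2 the type I interferon-stimulated genes turned (adjusted p = 0.295), and without AdGFP IFN-γ replicate 1 they (0.281) and the M2 surface markers (0.104) did not pass. MHC class II presentation was lost without AdGFP untreated replicate 1 (0.156) and AdGFP IFN-γ replicate 2 (0.0505), oxidative phosphorylation without the same libraries (0.144 and 0.174), and iron handling without AdGFP IFN-γ replicate 2 (0.215). Of the 23 named genes that passed, 18, 17, 14 and 18 kept the call without AdGFP untreated replicates 1 and 2 and AdGFP IFN-γ replicates 1 and 2, 19 without either AdMAF IFN-γ library, and 23 without either AdMAF untreated library. PSMB10, IL10 and C1QB were lost without AdGFP untreated replicate 1 (adjusted p = 0.0764, 0.0914 and 0.119) and without AdGFP IFN-γ replicate 1 (0.0926, 0.0521 and 0.16). PSME2, PSMB10, IL10 and IGF1 were lost without AdGFP untreated replicate 2 (0.071, 0.0904, 0.106 and 0.071). PSME2 and IGF1 were lost without AdGFP IFN-γ replicate 1 (0.132 and 0.1), and PSME2, PSMB10 and C1QB without AdGFP IFN-γ replicate 2 (0.0694, 0.0723 and 0.111). IL10 and C1QB were also lost without AdMAF IFN-γ replicate 1 (0.0622 and 0.0718) and replicate 2 (0.0616 and 0.0711).

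The IFN-γ effects of total RNA and of AdGFP shared genes. Of 341 genes higher with IFN-γ in total RNA and 140 under AdGFP, among 10303 tested in both, 63 were higher in both against 4.63 expected (Fisher's exact test, one-sided, p = 8.62e-57). Of 249 lower in total RNA and 120 under AdGFP, 58 were lower in both against 2.9 expected (p = 4.16e-63 in the same exact test). These tests treat genes as independent, which they are not. Across these genes the log2 changes correlated at Pearson's r = 0.66 (Spearman's rho = 0.59). The total RNA calls behind both counts were lost without untreated replicate 2 or IFN-γ replicate 2. The changes stayed about as large (GBP5 at 7.44 and 7.42, LGMN at −5.84 and −5.88). With only the 4 AdGFP libraries, 8 of 13 higher and 3 of 3 lower AdGFP genes were shared, against 0.419 and 0.0715 expected. The 3, named after their values were seen, were COL23A1, LTBP2 and S1PR1. The shared genes, higher and lower, numbered 67 and 36 without AdGFP untreated replicate 1, 32 and 22 without AdGFP untreated replicate 2, 29 and 13 without AdGFP IFN-γ replicate 1, 37 and 35 without AdMAF IFN-γ replicate 1, 37 and 34 without AdMAF IFN-γ replicate 2, and 40 and 19 without both AdGFP replicate 2 libraries.

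With added MAF, IFN-γ called 73 of 11171 genes, 55 higher and 18 lower. MAF, transgene included, was 629 ± 119.6 against 480.2 ± 408 RPKM (log2 change 0.70 ± 0.64, adjusted p = 0.694; −0.30 without AdMAF untreated replicate 2). GBP5 (5.43 ± 0.55, adjusted p = 0.0148), FAM26F (5.35 ± 0.48, adjusted p = 0.00853) and SOCS1 (5.30 ± 0.50, adjusted p = 0.0107) were the largest rises. SLC11A1 (−3.43 ± 0.35, adjusted p = 0.0148), the receptor GPR82 (−3.41 ± 0.48, adjusted p = 0.0389) and the scavenger receptor CD163L1 from 66.9 ± 21.5 to 8.31 ± 2.15 RPKM (−2.85 ± 0.38, adjusted p = 0.0365) were the largest falls. IRF1 rose by 3.92 ± 0.35, ANKRD22 by 5.23 ± 0.27, WARS by 4.81 ± 0.50 and SERPING1 by 3.05 ± 0.31. CD163 was 346 ± 52.9 against 1146 ± 25.9 RPKM (−1.73 ± 0.46, adjusted p = 0.18). MERTK was 62.6 ± 2.93 against 131 ± 4.54 RPKM (−1.06 ± 0.58, adjusted p = 0.49). At an unadjusted p under 0.05 stood 1485 genes against 559 by chance, and 47.9% did not overlap against 33.3% by chance. With 10929 genes run on simulated data, 18% of changes of log2 1, 86% of log2 2, 96% of log2 3 and 98% of log2 4 were recovered, with 15 unchanged genes called. The count was 31 and 7 without AdMAF untreated replicates 1 and 2, and 8 and 5 without AdMAF IFN-γ replicates 1 and 2. Of the 10 named genes that passed, 7, 1, 2 and 1 kept the call without these libraries in the same order. All of the 73 genes still tested (73, 73, 69 and 69) kept their direction, at a median of 1.04, 0.96, 1.01 and 0.99 of the log2 change. With no filter 33 genes passed (22 of them among the 73, with 4 of the 10 named genes), and with quantile normalization 127 (72, with all 10).

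By list, 10 of 24 moved with IFN-γ under AdMAF. IFN-γ response genes had 11 of 34 higher (24 adjusted over the list alone; median log2 change 2.90; adjusted p = 2.04e-28, adjusted p = 0.545 with an estimated correlation). The same estimated-correlation value of 0.545 applied to apoptosis regulators (median 0.69, adjusted p = 0.000138), MHC class I presentation (0 of 10 past limma, 3 over the list alone; median 0.77, 0.0115) and tryptophan and arginine metabolism (1 of 9 rose, median 1.12, 0.00612), which stood higher. It also applied to metallothioneins (0 of 9 past limma, 1 over the list alone; median −2.10, adjusted p = 0.000391; MT1G at 77.7 ± 54.7 against 907 ± 293 RPKM), efferocytosis and phagocytic receptors (5 lower and 1 higher over the list alone; −0.45, 0.00525), surface markers of M2 and M-CSF macrophages (2 lower over the list alone; −0.88, 0.00955) and iron handling (1 of 13 fell, −0.82, 0.0251), which stood lower. Genes for cholesterol synthesis and uptake (median −0.64, adjusted p = 0.00612) and glycolysis (−0.63, 0.00612; GAPDH at −1.02 ± 0.51) stood lower as well, each with an adjusted p of 0.712 with an estimated correlation. Calls were lost without AdMAF untreated replicate 1 (MHC class I, 0.103), AdMAF untreated replicate 2 (cholesterol 0.0876, iron 0.144, glycolysis 0.126), AdMAF IFN-γ replicate 1 (cholesterol 0.0623, glycolysis 0.0937) and AdMAF IFN-γ replicate 2 (MHC class I, 0.0852).

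Whether added MAF changes the response to IFN-γ is the interaction, and 0 of 11171 genes passed limma for it (358 at an unadjusted p under 0.05 against 559 by chance, lowest adjusted p 0.525). The chance level assumes that libraries vary independently. Same-number libraries deviated together within AdGFP and within AdMAF (r = 0.62 and 0.76 across genes). The low count therefore does not show that no gene differed. Differences in the IFN-γ effect (AdMAF minus AdGFP, log2) were 2.98 ± 0.90 for MAF, transgene included, 1.88 ± 0.82 for MERTK and −0.31 ± 0.65 for CD163, none past the test. CD163 was 0.02 without AdGFP untreated replicate 2 and 0.21 without AdGFP IFN-γ replicate 1. On simulated data with 10936 genes run, 2% of differences of log2 1, 32% of log2 2, 86% of log2 3 and 88% of log2 4 were recovered, with 5 unchanged genes called. By list, 10 of 24 differed (4, 6 and 6 without AdGFP IFN-γ replicate 1, AdMAF untreated replicate 1 and AdMAF IFN-γ replicate 1). Integrins and adhesion molecules responded lower under AdMAF than under AdGFP (12 of 16 below 0, median −0.77, adjusted p = 0.00259, adjusted p = 0.462 with an estimated correlation). They kept the call without each library. Metallothioneins were lower too (9 of 9 below 0, median −1.55, adjusted p = 0.00115, 0.857 with an estimated correlation; 0.404 without AdGFP IFN-γ replicate 1). So were IFN-γ response genes (32 of 34 below 0, median −0.54, adjusted p = 0.00087, 0.857 with an estimated correlation). The latter call was lost without AdGFP untreated replicate 2 (adjusted p = 0.362), AdGFP IFN-γ replicate 1 (0.228) and AdMAF untreated replicate 1 (0.0687).

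The genes that fell with IFN-γ in total RNA were followed into the other tables as 1 list of 261. After siMAF, 191 of 245 measured members stood lower (78%, against 47% of the other genes; median log2 change −0.25; adjusted p = 2.91e-18, adjusted p = 0.0647 with an estimated correlation). With IFN-γ under AdGFP 230 of 249 stood lower, 58 of them called (median −1.35; adjusted p = 4.55e-42, 0.0647 with an estimated correlation). Under AdMAF 203 stood lower, 9 of them called (median −0.66; adjusted p = 5e-17, 0.135 with an estimated correlation). In the interaction 191 of 249 were above 0, a smaller fall under AdMAF (median 0.53; adjusted p = 2.91e-18, 0.135 with an estimated correlation). For AdMAF against AdGFP with IFN-γ 149 stood higher, with 11 called higher and 1 lower (median 0.22; adjusted p = 0.000504, 0.341 with an estimated correlation; 0.185 without AdGFP IFN-γ replicate 1). For AdMAF against AdGFP without IFN-γ 170 stood lower (median −0.33; adjusted p = 4.66e-05, 0.316 with an estimated correlation). This last call was lost without AdGFP untreated replicate 2 (median −0.18, adjusted p = 0.527) and with the list rebuilt without untreated replicate 1 of total RNA (−0.25, 0.0588).

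**Figure D3:**
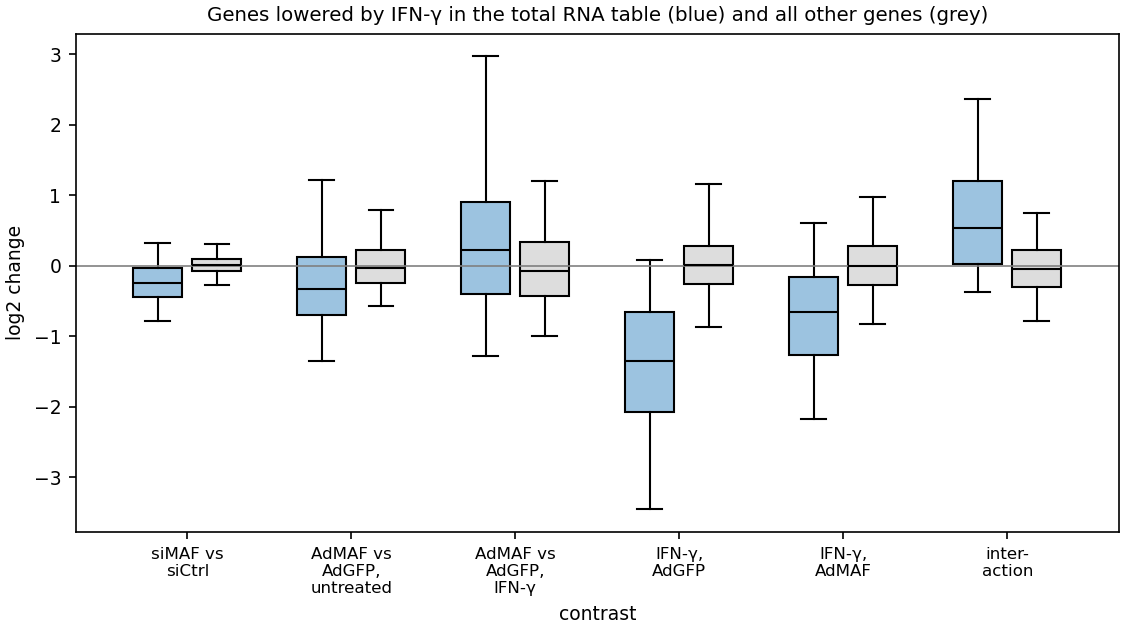
Log2 change (y axis) of the genes that fell with IFN-γ in total RNA (blue) and of all other genes (grey) in 6 contrasts of the siRNA and adenovirus tables (x axis); boxes show quartiles and the median, and whiskers the 5th to 95th percentile of genes. The blue medians were −0.25 with siMAF, −0.33 and 0.22 for AdMAF against AdGFP without and with IFN-γ, −1.35 and −0.66 for IFN-γ under AdGFP and AdMAF, and 0.53 for the interaction.

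The 200 genes lowest in siMAF, none of which passed on its own, shared 42 genes with the 261 that fell with IFN-γ in total RNA, against 4.72 expected among 10064 genes tested in both. MAF, SEPP1, RNASE1, GPR34, MS4A4A, CD200R1 and SLC40A1, chosen after their values were seen, were among them. With IFN-γ in total RNA 144 of 194 of the siMAF genes stood lower, 42 of them called lower and 12 called higher (median log2 change −0.74; adjusted p = 4.03e-11, adjusted p = 0.316 with an estimated correlation). Under AdGFP their median with IFN-γ was −0.35 (adjusted p = 5.39e-07, 0.234 with an estimated correlation), and under AdMAF −0.25 (0.000655, 0.316). For AdMAF against AdGFP it was −0.26 without IFN-γ (140 lower; adjusted p = 0.000138, 0.316 with an estimated correlation) and −0.14 with IFN-γ (adjusted p = 0.686). In the interaction it was 0.06 (56.8% above 0; adjusted p = 0.00635, 0.341 with an estimated correlation). The call without IFN-γ was lost without AdGFP untreated replicate 2 (−0.19, adjusted p = 0.207) and turned with the list rebuilt without siCtrl replicate 2 (−0.01, 0.945). With IFN-γ the comparison passed without AdGFP IFN-γ replicate 1 (−0.24, 0.0482). Its test turned with the list rebuilt without siMAF replicate 1 (0.02, 0.112) or siCtrl replicate 2 (0.14, 0.0344) and without AdGFP IFN-γ replicate 2 (0.06, 0.201) or AdMAF IFN-γ replicate 1 (−0.02, 0.844). The call under AdMAF was lost with the list rebuilt without siCtrl replicate 2 (−0.04, 0.183) or siMAF replicate 2 (−0.15, 0.119). The interaction was lost without siMAF replicate 2 (0.01, 0.132), AdGFP untreated replicate 2 (−0.01, 0.567), AdGFP IFN-γ replicate 1 (0.04, 0.818), AdMAF untreated replicate 1 (0.02, 0.0759) and AdMAF IFN-γ replicate 2 (−0.01, 0.126).

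Across all genes tested in both, the IFN-γ effect in total RNA correlated with the siMAF effect at Pearson's r = 0.38 (Spearman's rho = 0.38, 10064 genes; r = 0.18 without siMAF replicate 1 and 0.24 without siCtrl replicate 2). The MAF effects without and with IFN-γ correlated at r = 0.70 (rho = 0.68, 11171 genes; r = 0.43 without AdMAF untreated replicate 1). A donor difference between the viruses would enter both. The siMAF effect correlated with the MAF effect at r = 0.21 without IFN-γ (rho = 0.18, 10245 genes; r = 0.32, 0.01, 0.02 and 0.00 without siCtrl replicate 1, siMAF replicate 1, siCtrl replicate 2 and AdGFP untreated replicate 2) and at 0.01 with IFN-γ (rho = 0.00). These describe genes, which are not independent replicates, so no p is given.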

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

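The interaction and its list tests were planned, while the tests of an overall weaker IFN-γ response were chosen only after the result was seen. The results of this part were picked because the effect of IFN-γ differed between AdMAF and AdGFP by the interaction test itself. Values are medians over a list of the IFN-γ effect in AdMAF minus that in AdGFP (log2).

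The genes that fell with IFN-γ in total RNA fell less under AdMAF than under AdGFP (median difference 0.53, 191 of 249 above 0, adjusted p = 2.91e-18, adjusted p = 0.135 with an estimated correlation), which held without each library in turn. The list stood lower in AdMAF than in AdGFP without IFN-γ (median −0.33, mean −0.25, 170 of 249 lower, camera adjusted p = 4.66e-05). Without AdGFP untreated replicate 2 that median was −0.18. With IFN-γ the list stood higher in AdMAF (median 0.22, mean 0.44, camera adjusted p = 0.000504). Without AdGFP IFN-γ replicate 1 that median was 0.09. Neither passed the test with an estimated correlation (adjusted p = 0.316 and 0.341). By medians the untreated part was the larger and by means the IFN-γ part, so the split is not settled. The median difference of the IFN-γ effects was 0.5 in the lower and 0.65 in the higher of the 2 numbers. It was thus not confined to 1 number. The labels do not tie either number to 1 donor in both viruses, and each value rests on 1 library per group. A donor difference is therefore not decided. Open is an overall weaker response in the AdMAF libraries: the AdMAF median was 0.45 of the AdGFP median for 341 raised genes and 0.49 for 249 lowered genes, a difference of −0.04 (SE 0.07 over 2000 resamples of genes), while the fixed IFN-γ response genes kept 0.86 of their AdGFP median (3.36 under AdGFP and 2.90 under AdMAF), 0.38 more than the lowered genes (SE 0.1), so the lists of raised genes differ and do not decide. Donor differences between the viruses also stay open. In a check for mixed-up samples, 2 of 4 pairs of libraries with the same number and treatment did not match between the viruses. Across treatments within a virus, 0 of 4 same-number pairs mismatched. These counts point to 1 number, but a match does not show a shared donor. The design's biological explanation is that added MAF may keep these genes from falling. It is a hypothesis that no test here separates from a weaker response or from donor differences. A lower untreated level in AdMAF is not covered by that explanation. Its median of −0.33 was −0.18 without AdGFP untreated replicate 2, so it does not decide.

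IFN-γ response genes differed by −0.54 (adjusted p = 0.00087). MHC class I presentation gave −0.77 (adjusted p = 0.0355). Secreted M2 factors gave 0.48 (adjusted p = 0.042). Inflammatory cytokines and chemokines gave −0.76 (adjusted p = 0.0206). For lysosome and cathepsins the value was −0.46 (adjusted p = 0.0206). For glycolysis it was −0.48 (adjusted p = 0.0147). For oxidative phosphorylation it was −0.49 (adjusted p = 0.00259). Integrins and adhesion molecules differed by −0.77 (adjusted p = 0.00259). The Toll-like receptor pathway differed by −0.47 (adjusted p = 0.0438). Metallothioneins differed by −1.55 (adjusted p = 0.00115). The siMAF-lowered genes differed by 0.06 (adjusted p = 0.00635, 0.341 with an estimated correlation). With an estimated correlation the adjusted p was 0.462 for integrins and 0.857 for each of the other fixed lists named here, and 0 genes passed limma for the interaction (358 at an unadjusted p under 0.05).

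Most of these calls depended on single libraries, and those lost are given with their adjusted p. Without AdGFP untreated replicate 1 these were secreted M2 factors (0.0507) and oxidative phosphorylation (0.0557). Without AdGFP untreated replicate 2 they were IFN-γ response genes (0.362), MHC class I (0.203), secreted M2 factors (0.104), lysosome (0.104), glycolysis (0.979), the Toll-like receptor pathway (0.207), inflammatory cytokines (0.552, direction turned) and siMAF-lowered genes (0.567). Without AdGFP IFN-γ replicate 1 they were IFN-γ response genes (0.228), secreted M2 factors (0.225), lysosome (0.225), glycolysis (0.153), the Toll-like receptor pathway (0.624), metallothioneins (0.404), inflammatory cytokines (0.624, direction turned) and siMAF-lowered genes (0.818). Without AdGFP IFN-γ replicate 2 they were MHC class I (0.115) and oxidative phosphorylation (0.0503). Without AdMAF untreated replicate 1 they were IFN-γ response genes (0.0687), MHC class I (0.0687), secreted M2 factors (0.274), inflammatory cytokines (0.266), the Toll-like receptor pathway (0.133) and siMAF-lowered genes (0.0759). Without AdMAF untreated replicate 2 they were glycolysis (0.231), oxidative phosphorylation (0.231), lysosome (0.617) and the Toll-like receptor pathway (0.0519). Without AdMAF IFN-γ replicate 1 they were MHC class I (0.319), glycolysis (0.185), oxidative phosphorylation (0.197), lysosome (0.319) and the Toll-like receptor pathway (0.0972). Without AdMAF IFN-γ replicate 2 they were secreted M2 factors (0.439), the Toll-like receptor pathway (0.0793) and siMAF-lowered genes (0.126), and with that list rebuilt without siMAF replicate 2 they were the siMAF-lowered genes (0.132).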

How the results depend on the processing

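The replicate block within each virus and leaving out both AdGFP replicate 2 libraries were chosen only after the results were seen; the other alternatives were planned. Of the values that answer a comparison, 465 kept their direction and side of the threshold or stayed within range, 89 moved, 25 were no longer past the threshold, 1 newly passed and 10 reversed. Of single genes and lists, 2357 stayed, 513 were lost, 26 newly passed and 17 reversed. A pseudocount of 0.1, a prior without a trend and a fold of at least 2 moved no count of genes by more than 1.5 times, nor did that pseudocount any count of lists; the others were not run on lists. With 2 libraries per group and depth known only in part, small changes could not be tested for counting error. Leaving 1 library out left a lone sample that was assumed to vary like the other groups. Unless the construction shows it (fewer samples, more or fewer genes, a looser threshold), the cause was not tested.

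With no filter, 0 genes passed for AdMAF against AdGFP untreated, 51 genes and 8 lists for AdMAF against AdGFP with IFN-γ, 118 genes for IFN-γ under AdGFP and 33 under AdMAF, and the siMAF-lowered genes had an interaction median of 0.05 without passing. With an RPKM of at least 5, 6 lists passed for the interaction. With quantile normalization 76 genes passed for AdMAF against AdGFP with IFN-γ, 127 for IFN-γ under AdMAF and 6 lists for the interaction. The siMAF-lowered genes for AdMAF against AdGFP with IFN-γ had a median of −0.08 with quantile normalization and −0.08 with median centring, where the test reversed. At an adjusted p under 0.10, 1235 genes passed for IFN-γ in total RNA, 601 for AdMAF against AdGFP with IFN-γ, 557 for IFN-γ under AdGFP and 206 under AdMAF.

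With only the 4 libraries of a contrast, 1 gene passed for AdMAF against AdGFP untreated, 246 genes and 7 lists with IFN-γ, and 18 genes for IFN-γ under AdGFP. Without both AdGFP replicate 2 libraries, 0 genes passed limma for AdMAF against AdGFP untreated (428 at an unadjusted p under 0.05) and 0 with IFN-γ (1844), where 8 lists passed, and 113 for IFN-γ under AdGFP. For AdMAF against AdGFP untreated that setting reversed type I interferon-stimulated genes (adjusted p = 0.0373), inflammatory cytokines (0.0376) and CCL2 (−0.46), and gave −0.19 for IFN-γ-repressed and −0.19 for siMAF-lowered genes, neither past the test. The siMAF-lowered genes reversed to 0.06 for AdMAF against AdGFP with IFN-γ, and the correlations across genes were 0.55 for IFN-γ in total RNA and AdGFP, 0.00 for siMAF and MAF effect untreated, and −0.09 for siMAF and MAF effect with IFN-γ.

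With camera's estimated correlation, 0 lists passed in each of the 7 contrasts. A call lost there is not a measure of correlation between genes. The IFN-γ-repressed genes in siMAF had an estimated correlation of 0.008, under the preset 0.01. Their unadjusted camera p still went from 7.04e-19 to 0.0108. The IFN-γ-repressed genes kept their medians of −0.25 (siMAF, adjusted p = 0.0647), −0.33 (AdMAF against AdGFP untreated, 0.316), 0.22 (with IFN-γ, 0.341), −1.35 (IFN-γ under AdGFP, 0.0647), −0.66 (under AdMAF, 0.135) and 0.53 (interaction, 0.135) but not the call. The same held for siMAF-lowered genes at −0.74 (IFN-γ in total RNA, 0.316), −0.26 (AdMAF against AdGFP untreated, 0.316), −0.35 (IFN-γ under AdGFP, 0.234), −0.25 (under AdMAF, 0.316) and 0.06 (interaction, 0.341). With fry, 16 of the 19 lists that camera called for IFN-γ in total RNA passed. Lysosome and cathepsins (fry adjusted p = 0.0487) and dendritic cell markers (0.0113), which camera did not call, passed as well. For IFN-γ under AdGFP 1 list passed fry (IFN-γ response genes, adjusted p = 0.031), and 0 passed for each of the other contrasts.

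The replicate number as a block (a paired fit) gave 3804 genes for IFN-γ in total RNA, 709 for AdMAF against AdGFP with IFN-γ, 454 for IFN-γ under AdGFP, 155 under AdMAF and 3 for siMAF against siCtrl: MAF, SEPP1 and FOLR2 (adjusted p = 0.0319, 0.0319 and 0.0434). With that block 1940 genes had an unadjusted p under 0.05 for siMAF against siCtrl, against 512 unblocked. A block within each virus gave 1804 genes for IFN-γ under AdGFP, 1378 under AdMAF and 1 for the interaction. For the interaction 1724 genes then had an unadjusted p under 0.05, against 358 unblocked. The deviations of libraries with the same number correlated across genes at 0.85 in total RNA, 0.79 after siRNA, 0.62 within AdGFP and 0.76 within AdMAF, and at −0.05 to 0.23 across the viruses. This is a hint from the data, not from the labels, so the unblocked values stand as the results, and a call lost under the block is not evidence of a weaker effect.

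Leaving out each library in turn gave 0 to 185 genes for IFN-γ in total RNA, 0 to 4 for AdMAF against AdGFP untreated, 0 to 215 with IFN-γ, 70 to 258 for IFN-γ under AdGFP and 5 to 69 under AdMAF. Lists numbered 5 to 12 for siMAF, 4 to 8 for AdMAF against AdGFP with IFN-γ and 4 to 11 for the interaction. For siMAF, CD163 ran from −0.53 to 0.52, CCL2 from −0.49 to 2.04 and the adjusted p of metallothioneins from 3.09e-11 to 0.843. For AdMAF against AdGFP untreated, CD163 ran from −0.65 to 0.00, CCL2 from −0.46 to 5.31, and the adjusted p of type I interferon-stimulated genes from 3.99e-22 to 0.295 and of inflammatory cytokines from 2.56e-07 to 0.457. The adjusted p of type I interferon-stimulated genes ran from 3.54e-16 to 0.295 for IFN-γ under AdGFP, and that of inflammatory cytokines from 5.53e-09 to 0.624 for the interaction. CD163 ran from −0.83 to 0.21 in the interaction, and MAF from −0.30 to 1.69 for IFN-γ under AdMAF. The IFN-γ-repressed genes ran from −0.53 to −0.18 for AdMAF against AdGFP untreated and from 0.09 to 0.49 with IFN-γ. The siMAF-lowered genes ran from −0.41 to −0.01 and from −0.30 to 0.14 in the same contrasts, from −0.37 to −0.04 for IFN-γ under AdMAF and from −0.01 to 0.26 in the interaction. Correlations across genes ran from 0.45 to 0.72 for IFN-γ in total RNA and AdGFP, 0.18 to 0.36 for IFN-γ in total RNA and siMAF, 0.43 to 0.75 for the MAF effects without and with IFN-γ, 0.00 to 0.32 for siMAF and MAF effect untreated, and −0.09 to 0.10 for siMAF and MAF effect with IFN-γ.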

Other observations

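The tests of a few noncoding RNAs, of a single AdGFP library and of both AdGFP replicate 2 libraries were chosen only after the results were seen; the test of transcript length was planned before its result.

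The IFN-γ effects on a pair of gene lists are set side by side here across tables, without a test of the difference, since the tables were normalized separately. For neither list did the median rise in both numbers of total RNA and fall in both numbers of AdGFP. Genes for cholesterol synthesis and uptake had a median log2 change of 1.99 with IFN-γ in total RNA (adjusted p = 2.07e-14, adjusted p = 0.322 with an estimated correlation), but of −0.28 under AdGFP (adjusted p = 0.321) and −0.64 under AdMAF (adjusted p = 0.00612, 0.712 with an estimated correlation; 0.0876 without AdMAF untreated replicate 2 and 0.0623 without AdMAF IFN-γ replicate 1). Metallothioneins had medians of 2.65 with IFN-γ in total RNA (adjusted p = 2.85e-06, 0.339 with an estimated correlation), of −0.57 under AdGFP (adjusted p = 0.469) and of −2.10 under AdMAF (adjusted p = 0.000391, 0.545 with an estimated correlation). RPKM values of CXCL9 and CXCL10, which rose by 9.21 ± 0.40 and 7.82 ± 0.42 in total RNA, were not listed in the siRNA and adenovirus tables. Listed at 0 in every library were 4488 genes of the total RNA table, 4369 of the siRNA table and 3399 of the adenovirus table, and 236, 10 and 38 genes had a 0 in some library and at least 5 RPKM in another. In the check for mixed-up samples, 0 of 2, 0 of 2 and 0 of 4 pairs of libraries with the same number mismatched across treatments or siRNAs in the total RNA, siRNA and adenovirus tables. Between the viruses, 2 of 4 pairs with the same number and treatment did not match.

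The replicate numbers of the total RNA table differed across genes, with an SD of the log2 difference of 1.14 in untreated and 1.06 in IFN-γ libraries. RMRP and RPPH1, a pair of small noncoding RNAs, held 14.8% and 9.43% of the summed RPKM in untreated and IFN-γ replicate 2, and 0.0106% and 0.00319% in replicate 1. Their share alone would shift all other genes by 1 factor, and 45% and 42.4% of genes lay within 0.25 of the median difference. As only 39.5% to 75.1% did so in the groups of the other tables, these percentages do not decide. A shift by 1 factor adds no spread between genes, however, and the SDs of 1.14 and 1.06 stood above the 0.37 to 0.7 of those groups. This argues against the share of RMRP and RPPH1 as the cause of the spread. A bias by transcript length could not be told from other causes, as the difference correlated with length at Spearman's rho of 0.26 in untreated and 0.12 in IFN-γ libraries, over the 92.4% of genes with a matched length. A donor difference may add to it, and other causes, technical or biological, were not tested.

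Type I interferon-stimulated genes stood higher in AdMAF than in AdGFP without IFN-γ (median log2 change 1.22, adjusted p = 5.72e-06, 0.922 with an estimated correlation). Their median level (log2) was 7.95 and 4.46 in the untreated AdGFP libraries, 7.90 and 7.20 in the untreated AdMAF libraries, 8.49 and 6.54 in AdGFP with IFN-γ, and 8.30 and 8.20 in AdMAF with IFN-γ, so both AdGFP replicate 2 libraries stood lowest. Without AdGFP untreated replicate 2 the median change was −0.45 (adjusted p = 0.295), and without AdGFP untreated replicate 1, AdMAF untreated replicate 1 and AdMAF untreated replicate 2 it was 2.77, 0.75 and 1.69, while without both AdGFP replicate 2 libraries the list stood lower in AdMAF (adjusted p = 0.0373). The difference is consistent with a low level in AdGFP untreated replicate 2, which AdGFP IFN-γ replicate 2 shared in part and whose cause was not tested. An effect of added MAF on these genes stays open, as untested in more libraries.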
